A study of Mus musculus with 10 samples.

How the data were processed

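RNA from mouse colon was hybridised to 10 Agilent 2-colour arrays, 4 with whole colon tissue and 6 with colon organoids, which are cultures of colon epithelium grown in a gel from isolated crypts. Per the labels, the tissue came from male mice carrying Axin2CreERT2, a tamoxifen-inducible recombinase active in cells that express Axin2, and Trp53 alleles flanked by recombination sites. Mice received 2% dextran sodium sulfate (DSS), a detergent-like polymer that injures the colon epithelium, for 5 to 7 days, and tissue was taken 2 months after DSS. Organoids were grown from VillinCreERT2 mice with the same Trp53 alleles, treated with 800 nM 4OH-tamoxifen for 2 days, and KO cultures were selected with Nutlin-3A, which stops cells that have p53.

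Each tissue array set a KO mouse against a WT mouse. There were 2 such mouse pairs, and each pair was hybridised in both dye orientations. The 6 organoid arrays formed a loop over 6 samples, with 2 replicates each of WT, KO and KOWI. KOWI stands for KO organoids that the labels call Wnt-independent. They were grown without surrogate Wnt (sWnt, a protein that activates Wnt receptors) and without CHIR, an inhibitor of GSK3 that activates Wnt signalling. KOWI against KO therefore cannot tell the medium apart from adaptation to it or selection in it. The full medium held 0.328 nM sWnt, 3 µM CHIR, 25% R-spondin conditioned medium, 100 ng/ml noggin and 50 ng/ml EGF. Every organoid replicate 1 was labelled with Cy3 and every replicate 2 with Cy5, so dye and replicate cannot be told apart and share 1 term in the model. The labels number the mice separately, but do not say whether organoid replicates came from separate mice, so the organoid p-values measure only the spread between these samples, which may be technical. In 1 tissue label the replicate number of the Cy3 source differs from the title and the animal's own label; the title's number was used.

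Per the file headers, the authors scanned the arrays and extracted spot intensity with Agilent Feature Extraction 12.2.0.7 under the protocol GE2_1200_Dec17, array design 074809, with probe coordinates on the mouse build mm9. The mean intensity of each spot and the median of its local background were deposited without normalization. Per the file headers, the processed intensity was background-subtracted, spatially detrended and dye-normalized by linear and lowess steps, and the deposited log10 ratio is Cy5 over Cy3. The authors also deposited a log2 ratio per probe in the series' value table, for which the submitters' processing notes name limma without a version or steps. Its slope on the deposited scanner software ratios, put on the log2 scale, was between 0.970 and 1.00. Its direction was Cy5 over Cy3, and its column medians ran from -0.000351 to 0.0173. How it was centred stays unknown.

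The ratios analysed here were computed in R 4.3.3 with limma 3.58.1 from the mean and background intensities: normexp background correction with an offset of 50, then loess within each array, with control spots and spots marked as outliers by the scanner software given no weight. Of 62976 spots, 3671 were controls. Outlier spots were set to missing. They were 0.808% and 2.18% of spots on the organoid arrays with KO and WT, and 13.7% to 16.3% on the 4 organoid arrays with KOWI. Spots of 1 probe were averaged. Of 56605 probes, 35405 were named by RefSeq accession, 9124 by symbol and 25 by synonym through a RefSeq table of assembly GRCm38.p6, used for names only, and 12051 had no name there. A gene was represented by the probe with the highest mean intensity. A gene was tested if its probe was well above background in every channel of at least 1 group and had no missing value that prevented the fit. Outlier spots removed 909 of 14061 genes in tissue and 3407 of 14747 in organoids.

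In tissue, the dye-swapped arrays of each pair were turned the same way and averaged, and the 2 pair ratios were tested against 0 with limma (lmFit and eBayes). In organoids, the ratios were first fitted by least squares to 6 sample values, and these were tested with limma for group with the replicate number as a term. All p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The sample, not the array, was the replicate, and the number of arrays limits the precision. The fit to sample values overstates purely technical noise, whereas a fit that treats the arrays as independent understates it where samples differ: the median residual variance of sample values was 0.0349, against a median squared residual of the loop of 0.00952. The loop residual has 1 degree of freedom, which puts its median well below its mean. The means were 0.0661 and 0.0307, a smaller gap. Tissue and organoid arrays were on separate slides scanned separately, so tissue and organoid levels cannot be compared and only ratios within arrays were. Within each experiment there was 1 slide.

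Changes planted in simulated data were recovered to an extent that depends on the simulated spread. With each gene's variance drawn from the distribution that limma fitted to the real data, the tissue test recovered 0 of 98 genes changed by 1 on the log2 scale and 0 of 102 changed by 2, with 0 false calls among 13152 genes, so 0 calls in tissue do not show that 2-fold or 4-fold changes are absent. The organoid tests over 11340 genes then recovered 0.909% for KO against WT (6 false calls), 2.94% for KOWI against WT (2) and 14.2% for KOWI against KO (9) at a change of 1, and 82.2%, 83.7% and 88.2% at a change of 2. With the shrunken variances, which differ less between genes than the real ones, the tissue test recovered 98.0% at a change of 1 (30 false calls) and the organoid tests 43.6%, 62.7% and 79.1%, which overstates what the real data allow.

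Ratios were smaller for bright probes. The median absolute log2 change in tissue was 0.20 for genes with a mean log2 intensity of 8 to 10 and 0.03 above 16. For genes with 1 probe over 14 and another under 12 whose change exceeded 0.7, the bright probe showed a median of 0.301 of the dim probe's change in tissue (15 genes) and 0.264 in KOWI against WT organoids (42 genes), against 0.910 (66 genes) and 0.944 (196 genes) where both probes were under 12. Probes at 12 to 14 showed 0.535 (27 genes) and 0.739 (65 genes) of the change of probes under 12, so ratios are shrunken in part below 14 too. At most 1 spot per array was marked as saturated. Folds of bright genes are therefore lower than those of dim probes of the same gene. Counts of changed genes, gene lists, the comparison of tissue with organoids and the correlation of KO with KOWI ratios were also computed with probes under a log2 intensity of 14, an alternative added after the data were seen.

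Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation, camera relies on the few residual degrees of freedom that 2 replicates leave. A list could then hardly pass after adjustment whatever its values, so a high p there does not count against a list. The preset correlation in turn gives p-values that are too low where members are more correlated. In tissue the estimates ran from -0.0667 to 1. There were 28 lists with 589 entries, of which 587 had a probe. Lists with fewer than 3 tested members were not tested, a limit set after the data were seen. Genes named in the text follow a rule set before the data were examined. Per comparison these were the 12 highest and 12 lowest fold changes among genes past the threshold with the same sign in both replicates. Where fewer than 5 genes passed, they were the 10 higher and 10 lower genes with the smallest p. Up to 4 passing members of each list were added (up to 2 by smallest p if none passed), and Trp53, Cdkn1a, Mdm2, Axin2, Lgr5, Ly6a, Clu and Mki67 always. Predicted gene models were not named, and the text leaves out some members of lists without a call. Any other named gene was chosen after its values were seen. Where a probe was not well above background on any array of a group, the fold is given as "at least N-fold": the brighter group's mean against the dim group's, each dim spot raised to the lowest signal that was well above background. This uses channel means, which dye can bias, so it is given only where it does not exceed the fold from the ratios within arrays. Alternatives covered background correction, source of the ratios, filters, probes per gene, the variance prior, scaling, the unit of replication, the replicate block, the shared spread, outlier spots and leaving out each replicate.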

Results

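Transcript levels were measured on 10 two-channel arrays in colon tissue after DSS injury (2 KO and 2 WT mice, 4 arrays) and in colon organoids (2 samples each of WT, KO and KOWI, 6 arrays). Trp53 encodes p53, a transcription factor that halts the cell cycle or triggers cell death after damage. The series title places the study in the question of how p53 ends the regenerative state after colitis-like injury. Between 44.6% and 59.1% of spots in a channel were well above background.

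Trp53 itself was the targeted gene. Its probe lies on mm9 chromosome 11 from 69403134 to 69403193; whether that stretch is part of the deleted exons was not checked, so the probe may not report the deletion. In tissue its log2 KO over WT was -0.46 in pair 1 and 0.04 in pair 2 (mean -0.21, SE 0.17, limma adjusted p = 0.614). In organoids it was well above background in both WT samples and not in any KO or KOWI sample. The log2 ratio to WT was -1.07 and -0.59 in the KO replicates (mean -0.83, limma adjusted p = 0.587) and -0.95 and -0.64 in the KOWI replicates (mean -0.79, limma adjusted p = 0.0785). The dim groups' signal limits both ratios, and no bound on the fold is given, since the one from channel means exceeded the ratio within arrays.

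In KO colon tissue 2 months after DSS, goblet cell and colonocyte markers lay below WT and fibroblast and smooth muscle markers above it, in both mouse pairs. Markers of other cell types moved with them, in lists added after the data were seen: 0 of 18 general epithelium genes were positive (median -0.14), against 23 of 23 skeletal muscle genes (0.54) and 14 of 14 cornified skin genes (0.26). Goblet cell markers, the genes of mucus-secreting cells, were negative for 23 of 24 genes with a median log2 of -0.19 (camera adjusted p = 2.11e-06; adjusted p = 0.835 with an estimated correlation), among them Spdef at -0.83 (SE 0.08) and Rep15 at -0.82 (SE 0.09). Colonocyte markers, the genes of absorptive cells, were negative for 25 of 29 (median -0.20, camera adjusted p = 8.36e-06; adjusted p = 0.835 with an estimated correlation), among them the chloride exchanger Slc26a3 at -0.56 (SE 0.06). All 16 fibroblast markers were positive, with a median of 0.30, among them Lum, a collagen-binding proteoglycan, at 1.58 (SE 0.15), and Fap, a protease of activated fibroblasts, at 0.90 (SE 0.08). The fibroblast list had a camera adjusted p of 8.36e-06 and an adjusted p = 0.835 with an estimated correlation. With probes under a log2 intensity of 14, since brighter probes gave small ratios, the medians were -0.39 for goblet cell, -0.43 for colonocyte, 0.54 for fibroblast and 0.32 for smooth muscle markers.

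No single gene passed the threshold in tissue: limma called 0 of 13152 genes (smallest adjusted p = 0.256), 1930 genes had an unadjusted p under 0.05 where chance gives 658, and limma on the 4 arrays taken as independent called 601. In simulated data with the real spread of variances the test found 0 of 102 genes changed by 2 on the log2 scale, so changes of this size can be missed. The values below are therefore not calls. The highest values among genes with the smallest p were Mylk4, a muscle-type kinase (log2 3.47, SE 0.14), Wfdc21 (2.33, SE 0.10), Sult1e1, an estrogen sulfotransferase (2.22, SE 0.08), Tmem182 (1.92, SE 0.06) and Unc45b, a myosin chaperone (1.69, SE 0.06), each at adjusted p = 0.256. Mettl21c was at 1.60, Klhl31 and Ctxn3 at 1.58, Ppp1r3c, which targets phosphatase to glycogen, at 1.41, and Klhl13 at 1.35. On the other side stood Gcg, which encodes glucagon and GLP-1 (-1.24, SE 0.09), Rprm (-1.10, SE 0.07), Rnf32 (-1.10), Lix1 (-1.04), the enteroendocrine transcription factor Neurod1 (-1.01, SE 0.07), Gcnt3, which branches mucin glycans (2.01-fold lower), Ttll6 (2.00-fold lower), the mineralocorticoid receptor Nr3c2 (-0.86), Chga, a granule protein of enteroendocrine cells (-0.82, SE 0.06) and Miat (-0.81). In both pairs 81 genes were over 2-fold higher and 17 over 2-fold lower, and the pairs' log2 ratios correlated across genes with r = 0.532, genes not being independent replicates.

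Enteroendocrine markers, the genes of hormone-producing cells, had 14 of 17 negative values and a median of -0.26 (camera adjusted p = 0.000102), and 4 were lower when adjusted over the list alone, against 0 over all genes. Colonic stem cell markers had a median of -0.18 (camera adjusted p = 0.0124), with Sox9 at -0.94 and Aqp4 at -0.88, and 2 lower and 1 higher when adjusted over the list alone. Interferon-stimulated genes had a median of -0.17 (camera adjusted p = 0.0151), with Oasl2 at -0.51 and Ifi27l2a at 0.72. The other lists called on the higher side were smooth muscle (15 of 15 positive, median 0.16, adjusted p = 0.000102), squamous epithelium (15 of 15, 0.25, adjusted p = 0.000459), adipocytes (7 of 7, 0.50, adjusted p = 0.00229, with Plin4 at 0.95), YAP target genes (18 of 22, 0.25, adjusted p = 0.00491, with Lats2 at 0.59), endothelium (8 of 8, 0.34, adjusted p = 0.0184) and T cells (11 of 13, 0.21, adjusted p = 0.0474). Each of these 9 lists, like the 3 above, had adjusted p = 0.835 with an estimated correlation. Tests without 1 mouse used separate channels without the pairing. With no mouse left out, that setting called 11 lists against 12 with pairs, so a lost call need not come from the mouse alone. Leaving out WT replicate 1 ended the calls of stem cell markers (list mean 0.155, adjusted p = 0.763), interferon-stimulated genes (adjusted p = 0.432), squamous epithelium (adjusted p = 0.432) and adipocytes (adjusted p = 0.333). Leaving out WT replicate 2 ended those of T cells (list mean -0.131, adjusted p = 0.741), endothelium (adjusted p = 0.506) and smooth muscle (adjusted p = 0.500). Without KO replicate 1 smooth muscle (adjusted p = 0.913) and T cells (adjusted p = 0.284) were not called. Without KO replicate 2 stem cell markers (list mean -0.0293, adjusted p = 0.583), adipocytes (list mean -0.191, adjusted p = 0.826), T cells (adjusted p = 0.0901) and endothelium (adjusted p = 0.0790) were not. The pair medians were -0.41 and -0.04 for stem cell markers and 0.02 and 0.56 for endothelium. Lists without a call were macrophages (median 0.25, adjusted p = 0.0631), tuft cells (0.28, 0.0737), neutrophils (0.21, 0.111), neurons and glia (0.09, 0.111), immediate early genes (0.09, 0.111), host defence (-0.05, 0.111), B and plasma cells (-0.19, 0.259), oxidative phosphorylation (-0.02, 0.287), cholesterol synthesis (0.00, 0.557), glycolysis (-0.01, 0.798), MHC class II (0.03, 0.798) and heat shock (-0.01, 0.979).

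p53 target genes did not stand apart in tissue. Of 37 measured, 21 were positive and 16 negative (median 0.04, camera adjusted p = 0.835), with Gdf15 at -0.47, Apaf1 at -0.39, the cell cycle inhibitor Cdkn1a at -0.14 and Mdm2, the ligase that degrades p53, at 0.02. Fetal-like and regenerative epithelium genes had a median of 0.07 (23 of 33 positive, camera adjusted p = 0.0702). They included Ereg, an EGF receptor ligand, at 0.77, Vsig1 at -0.53, Ly6a at -0.09 and Clu at 0.05. Wnt target genes had a median of -0.06 (camera adjusted p = 0.478), with pair medians of -0.42 and 0.14. They were called higher without WT replicate 1 (list mean 0.737, camera adjusted p = 0.00652) and lower without WT replicate 2 (-0.957, 0.000746) or KO replicate 1 (-0.677, 0.0444), so their direction depends on the mouse. Among them were Cdx2, an intestinal identity factor, at -1.08, Axin2 at -0.18 (pairs -0.46 and 0.11) and the stem cell receptor Lgr5 at -0.43 (pairs -1.04 and 0.18). Cell cycle genes had a median of -0.03, with Mki67 at -0.02. Ly6a, Clu, Mdm2 and Mki67 were read from probes with log2 intensities of 15.9 to 16.8, where ratios are small for nearly all genes. With probes under 14 the fetal-like list had a median of 0.38 over 13 genes (camera adjusted p = 0.0415; adjusted p = 0.759 with an estimated correlation) and p53 targets -0.01 over 29. Macrophage markers were then called too (median 0.25, camera adjusted p = 0.0333; adjusted p = 0.762 with an estimated correlation), while squamous epithelium (5 genes, median 0.45, camera adjusted p = 0.0928) and T cells (camera adjusted p = 0.0627) no longer were. Interferon-stimulated genes had a median of -0.32 with these probes.

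In KO organoids in full medium, p53 target genes lay below WT and cell cycle genes above it. As KO cultures were selected with Nutlin-3A, these ratios cannot tell that selection apart from the loss of Trp53. Of 34 p53 targets, 27 were negative, with a median log2 of -0.31 in KO over WT and medians of -0.30 in each replicate (camera adjusted p = 7.67e-14; adjusted p = 0.167 with an estimated correlation; fry adjusted p = 0.0165). When adjusted over the list alone, 6 p53 targets were lower, among them Psrc1, a microtubule-associated protein (-1.80, SE 0.17), Zmat3, an RNA-binding protein (-1.48, SE 0.16) and Phlda3, an inhibitor of AKT (-2.26), against 0 over all genes. Cdkn1a was at -0.27 and Mdm2 at -0.20. Of 31 cell cycle genes 30 were positive, with a median of 0.49 (camera adjusted p = 9.04e-08; adjusted p = 0.626 with an estimated correlation; camera adjusted p = 0.292 without WT replicate 2), among them the kinase Ttk at 0.90, Foxm1, which drives mitotic genes, at 0.83 and Mki67 at 0.50.

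**Figure D1:**
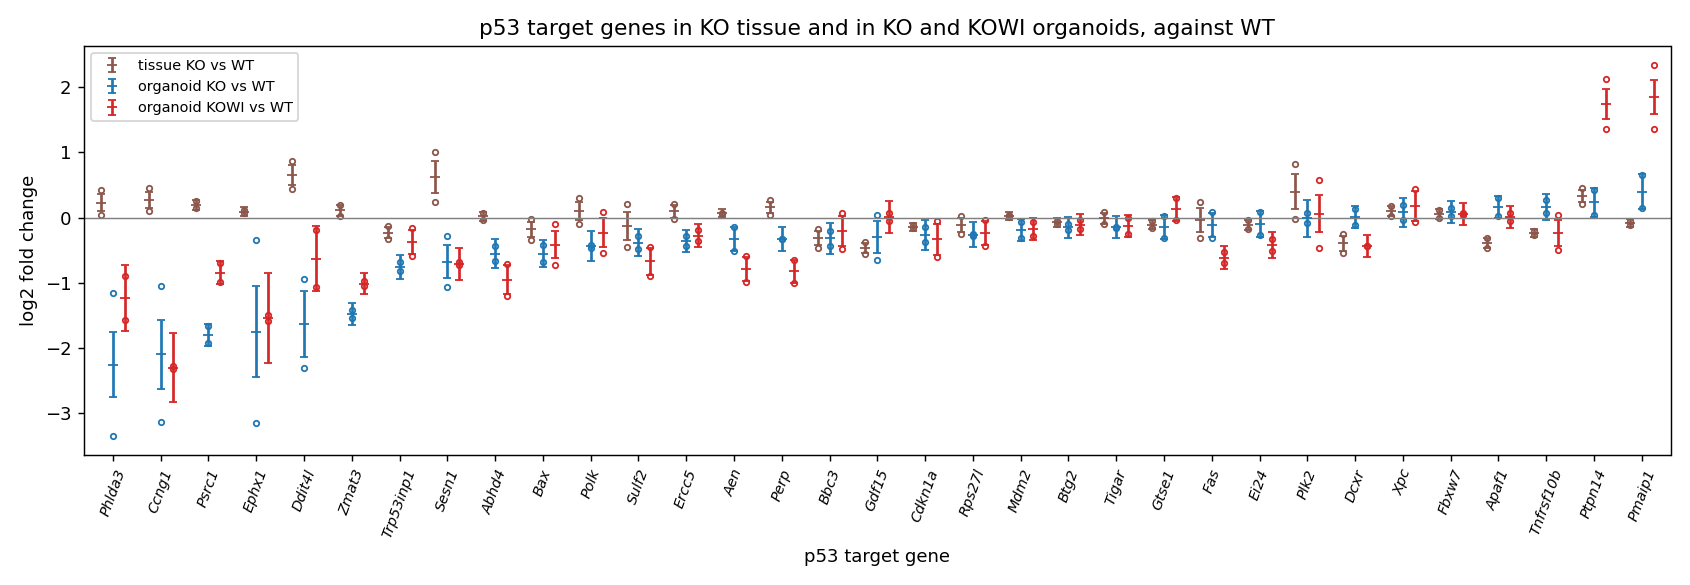
The 33 p53 target genes measured in both experiments (x axis, ordered by the value in KO organoids), with log2 fold change against WT on the y axis for KO tissue, KO organoids and KOWI organoids. Dashes are means with SE and circles the 2 pairs or replicates; Psrc1 and Zmat3 were at -1.80 and -1.48 in KO organoids and at 0.19 and 0.11 in KO tissue.

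Markers of secretory cells were above WT in KO organoids and those of colonocytes below. Goblet cell markers were positive for 20 of 21 genes (median 0.40, camera adjusted p = 2.63e-06; adjusted p = 0.282 with an estimated correlation), with Atoh1, the secretory lineage factor, at 0.98 and Rep15 at 0.54. Enteroendocrine markers were positive for 10 of 11 (median 0.54, camera adjusted p = 0.00745; adjusted p = 0.626 with an estimated correlation), with Scg2 at 1.35 and Neurod1 at 0.93. Colonocyte markers were negative for 24 of 28 (median -0.49, camera adjusted p = 2.58e-12; adjusted p = 0.167 with an estimated correlation), with Guca2a, which encodes guanylin, at -0.88 and the mucin Muc3 at -0.70. Epithelial host defence genes had a median of 0.21 (camera adjusted p = 0.0122; adjusted p = 0.493 with an estimated correlation; fry adjusted p = 0.0165), and 6 were higher when adjusted over the list alone, among them the antimicrobial lectin Reg3b (2.71, SE 0.16) and the neutrophil attractant Cxcl5 (1.86, SE 0.19). With probes under 14 the host defence median was 0.83 over 17 genes (camera adjusted p = 7.19e-05; adjusted p = 0.330 with an estimated correlation), and oxidative phosphorylation, with 4 genes left, was not called (camera adjusted p = 0.861). Stem cell markers had a median of 0.24 (camera adjusted p = 0.0116; adjusted p = 0.626 with an estimated correlation), with Lgr5 2.83-fold above WT (log2 SE 0.19) and Smoc2 at 2.16 (SE 0.44). Wnt target genes had a median of 0.21 (camera adjusted p = 0.0311; adjusted p = 0.626 with an estimated correlation), with Nkd1 at 0.54 and Axin2 at 0.31. Oxidative phosphorylation genes had a median of -0.05 (camera adjusted p = 0.0129; adjusted p = 0.829 with an estimated correlation), and their mean turned to 0.104 without KO replicate 1 (adjusted p = 0.762). Without WT replicate 1 the calls of goblet (adjusted p = 0.0686), enteroendocrine (0.280), Wnt (0.280) and oxidative phosphorylation genes (0.0846) were lost. Without KO replicate 1 those of enteroendocrine (0.696), stem cell (0.696) and Wnt genes (0.753) were lost. Oxidative phosphorylation was not called without WT replicate 2 (0.577), nor Wnt targets without KOWI replicate 2 (0.0639). YAP targets (median 0.19, camera adjusted p = 0.393) and fetal-like genes (0.17, camera adjusted p = 0.0676) did not pass, with Ereg at -2.90 (SE 0.51), Ly6a at 0.17 and Clu at -0.10. Interferon-stimulated genes had a median of 0.24 (camera adjusted p = 0.231), 0.58 in replicate 1 and -0.09 in replicate 2, with Cxcl10 at 1.28. The other 11 lists tested had camera adjusted p-values from 0.372 to 0.935.

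No gene passed between KO and WT organoids: limma called 0 of 11340 genes (smallest adjusted p = 0.0645), 607 had an unadjusted p under 0.05 where chance gives 567, and limma on the arrays taken as independent called 710. Values with the smallest p on the higher side were Reg3b, the sialyltransferase St8sia4 (1.87), Cxcl5, the Wnt receptor Ror2 (1.75), Cdkn2a, which encodes p16INK4A and p19ARF (1.70, SE 0.17), H2bu2 (1.59), Zscan4c, a gene of the early embryo (1.43), Tgif2 (1.36), Ccn3 (2.13) and Lgr5. On the lower side were the DNA repair enzyme Mgmt (-2.12, SE 0.26), Osr2 (-2.05), Zfp365 (-1.96, SE 0.16), Ugt2b5 (-1.95), Psrc1, the carboxylesterase Ces2e (-1.80), Bche, a cholinesterase (-1.68), Zmat3, Nat8f5 (-1.22) and the amino acid transporter Slc6a19 (-1.03). The 2 replicate ratios correlated across genes with r = 0.207. Without KOWI replicate 1 the count was 10 and without KO replicate 1 it was 3.

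In KOWI organoids, without Trp53 and without sWnt and CHIR, the colonocyte list lay below WT in full medium and the lists of YAP targets and regenerating epithelium above it, with a minority of the latter 2 lists' genes passing. Colonocyte markers fell for 14 of 28 genes, and 27 of 28 were negative, with a median log2 of -1.60. The list's camera adjusted p was 6.35e-15, or 0.270 with an estimated correlation, and its fry adjusted p was 0.0275. Muc3 fell 14.8-fold (log2 -3.88, SE 0.17, limma adjusted p = 0.00658), the water channel Aqp8 13.7-fold (log2 SE 0.30), the sodium-proton exchanger Slc9a3 12.5-fold (SE 0.28) and Tmigd1 8.66-fold (SE 0.49). YAP target genes, which respond to the Hippo pathway's effector, rose for 7 of 22 and fell for 0 (median 0.78, camera adjusted p = 0.000378; adjusted p = 0.552 with an estimated correlation). Among them were the matrix proteins Ccn2 (2.39, SE 0.39) and Ccdc80 (2.15, SE 0.25), the phosphatase Ptpn14 (1.74, SE 0.23) and the transcription factor Foxf2, at least 3.00-fold higher since it was not well above background in WT. Fetal-like and regenerative epithelium genes rose for 5 of 32 and fell for 1 (median 0.28, camera adjusted p = 0.000385; adjusted p = 0.552 with an estimated correlation). The secreted phosphoprotein Spp1 rose 31.7-fold (log2 4.99, SE 0.60, limma adjusted p = 0.0217), Ptgs2, the inducible cyclooxygenase, 4.31-fold and Phlda1 3.64-fold, whereas Ereg fell 7.99-fold. Clu was at 1.49 (SE 0.31, limma adjusted p = 0.0591) and Ly6a at 0.84 (SE 0.23, limma adjusted p = 0.0990).

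Stem cell markers rose for 3 of 15 and fell for 1 (median 0.41, camera adjusted p = 0.00862; adjusted p = 0.552 with an estimated correlation): Lgr5 rose 7.05-fold (log2 2.82, SE 0.19), Sox9 3.47-fold and Nrn1 3.43-fold, and the water channel Aqp4 fell 16.8-fold. Wnt target genes rose for 3 of 18 (median 0.36, camera adjusted p = 0.0188; adjusted p = 0.552 with an estimated correlation), namely Lgr5, the Wnt antagonist Nkd1 (2.82-fold) and the transcription factor Tcf7 (2.09-fold). Axin2 was at 0.85 (SE 0.21, limma adjusted p = 0.0878). Goblet cell markers fell for 3 of 21 (median -0.59, camera adjusted p = 0.000119; adjusted p = 0.363 with an estimated correlation): Fcgbp 2.87-fold, the goblet cell factor Spdef 2.32-fold and Rep15 2.12-fold. Enteroendocrine markers had a median of -0.56 with none passing (camera adjusted p = 0.0110; adjusted p = 0.552 with an estimated correlation). Oxidative phosphorylation genes were negative for 25 of 26 (median -0.28, camera adjusted p = 0.000328; adjusted p = 0.612 with an estimated correlation), and Sdha, a subunit of succinate dehydrogenase, fell 2.68-fold. Cell cycle genes were positive for 29 of 31 (median 0.55, camera adjusted p = 0.000385; adjusted p = 0.612 with an estimated correlation) with none passing, Mki67 at 0.27, and their medians were 0.02 in replicate 1 and 1.01 in replicate 2. Without KOWI replicate 2 the calls of stem cell (adjusted p = 0.772), Wnt (0.527), cell cycle (0.518), oxidative phosphorylation (0.243) and enteroendocrine genes (0.0548) were lost. Wnt targets were also not called without WT replicate 1 (0.0802) or KO replicate 1 (0.0584). With probes under 14 the medians were 0.78 for stem cell markers and 0.71 for Wnt targets, oxidative phosphorylation was not called (4 genes, camera adjusted p = 0.260), and cholesterol synthesis genes were called lower (median -0.24, camera adjusted p = 0.0208; adjusted p = 0.410 with an estimated correlation).

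p53 target genes in KOWI were negative for 26 of 34 against WT (median -0.36, camera adjusted p = 0.000181; adjusted p = 0.363 with an estimated correlation; fry adjusted p = 0.0482). Zmat3 fell 2.03-fold, while Pmaip1, which encodes the cell death factor NOXA, rose 3.62-fold and Ptpn14, also on the YAP list, 3.35-fold. Cdkn1a was at -0.33 and Mdm2 at -0.18. Adjusted over the list alone, 7 p53 targets were lower and 2 higher. Adjusted over the list alone, 17 colonocyte markers were lower, 10 YAP targets higher and 1 lower, and 11 fetal-like genes higher and 1 lower. In host defence genes the secreted receptor Dmbt1 fell 5.33-fold and Nlrp6 2.55-fold, while Cxcl5 rose 3.50-fold (list median -0.26, camera adjusted p = 0.304). Single genes of other lists that rose were Ptgs1, a cyclooxygenase of tuft cells (6.69-fold), the phosphatase Dusp1 (5.36-fold), Cxcl10 (3.59-fold), the glycolysis genes Pfkfb3 (2.67-fold) and Pgk1 (2.19-fold), Lck (2.57-fold), Uchl1 (at least 1.78-fold), H2-DMb1 (2.22-fold) and Cd68 (1.82-fold). Klf4, a factor of differentiated epithelium, fell 2.59-fold, Fbln1 3.28-fold and Hmgcs1 of cholesterol synthesis 1.90-fold. The 13 lists tested without a call, host defence among them, had camera adjusted p-values from 0.164 to 0.945.

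In all, limma called 611 of 11340 genes between KOWI and WT, 380 higher and 231 lower, with 2620 at an unadjusted p under 0.05. The largest rises after Spp1 were Gpm6b (log2 3.65), St8sia4 (3.53), Bend4 (3.09), Zscan4c (3.02), H2bu2 (2.91), the actin regulator Enah (2.90), Zscan4a (2.87), the actin-binding protein Cald1 (2.85), Lgr5, Ptgs1 (2.74) and Pros1 (2.72). Zscan4 genes are near-identical copies whose probes can share signal. The largest falls were Aqp4 (-4.07, SE 0.72), Hao2 (-3.94), Muc3, the aminopeptidase Enpep (-3.87), Aqp8, the trypsin inhibitor Spink1 (-3.75), Slc9a3, Sval1 (-3.38), Sult1b1 (-3.30), Bche (-3.14), Tmigd1 and Osr2 (-3.11). The count was 59 with outlier spots kept, 134 with the scanner software's log ratios and 4211 with arrays taken as independent. Separate channel values gave 173 higher and 443 lower with the replicate block and 202 higher and 586 lower without it, so the share of higher genes depends on whether ratios or separate channels are tested. Without KOWI replicate 2 the count was 19, without WT replicate 1 it was 56, without KO replicate 2 it was 72 and without WT replicate 2 it was 105.

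In KOWI organoids, Wnt-independent and grown without sWnt and CHIR, transcripts of differentiated cells lay below those of KO organoids in full medium. Colonocyte markers fell for 7 of 28 genes (median -0.90). The list's camera adjusted p was 6.74e-12, or 0.195 with an estimated correlation, and its fry adjusted p was 0.0310. Aqp8 fell 9.74-fold (log2 -3.28, SE 0.30, limma adjusted p = 0.0311), Muc3 9.05-fold and Slc9a3 8.27-fold. Lypd8, which keeps bacteria from the epithelium, fell 4.30-fold. Goblet cell markers were negative for 21 of 21 genes (median -1.02, camera adjusted p = 1.11e-12; adjusted p = 0.195 with an estimated correlation; fry adjusted p = 0.0225) and 2 fell, Rep15 and Fcgbp, each 3.08-fold. Enteroendocrine markers were negative for 10 of 11 (median -0.95, camera adjusted p = 7.69e-06; adjusted p = 0.439 with an estimated correlation), and Neurod1 was not well above background in KOWI (limma adjusted p = 0.0597). Host defence genes had a median of -0.41, with Dmbt1 falling 6.21-fold and Reg3b 5.27-fold. The list's camera adjusted p was 0.000108, or 0.331 with an estimated correlation, and its fry adjusted p was 0.0139. Oxidative phosphorylation genes were negative for 26 of 26 (median -0.18, camera adjusted p = 0.00507; adjusted p = 0.713 with an estimated correlation), although replicate 1 had a median of 0.01 and replicate 2 of -0.47. This call was lost without KO replicate 2 (adjusted p = 0.568) and, with the direction against other genes turned, without KOWI replicate 2 (list mean -0.0303, adjusted p = 0.879).

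YAP target genes (median 0.32, 18 of 22 positive, camera adjusted p = 7.69e-06; adjusted p = 0.439 with an estimated correlation) and fetal-like genes (0.13, 23 of 32, camera adjusted p = 0.000130; adjusted p = 0.580 with an estimated correlation) were above KO in full medium. Tgfb2, a growth factor of the TGF-beta family, rose 2.72-fold and Phlda1 2.82-fold. Clu was at 1.59 (replicates 0.97 and 2.21, limma adjusted p = 0.0994) and Ly6a at 0.67. Wnt target genes were not called lower in KOWI than in KO organoids. Their median was 0.07 (11 of 18 positive, replicates -0.08 and 0.55, camera adjusted p = 0.0710), with Lgr5 at 1.32 (SE 0.19, limma adjusted p = 0.0675), Nkd1 at 0.95 and Axin2 at 0.54 (SE 0.21). p53 targets had a median of 0.04 (camera adjusted p = 0.404), cell cycle genes 0.04 (camera adjusted p = 0.541), and Mki67 was at -0.23, Cdkn1a at -0.07 and Mdm2 at 0.02. Stem cell markers had a median of 0.07 (replicates -0.03 and 0.56, camera adjusted p = 0.0660), and 1 of them, Nrn1, rose 2.91-fold. With probes under a log2 intensity of 14, Wnt targets had a median of 0.27 over 16 genes (camera adjusted p = 0.0209; adjusted p = 0.521 with an estimated correlation) and stem cell markers 0.24 (camera adjusted p = 0.0152; adjusted p = 0.384 with an estimated correlation). Cholesterol synthesis genes were then called lower (11 of 12 negative, median -0.22, camera adjusted p = 0.0209; adjusted p = 0.380 with an estimated correlation), oxidative phosphorylation was not called (4 genes, camera adjusted p = 0.201), and the medians were 0.34 for fetal-like and -0.64 for host defence genes. Adjusted over the list alone, 12 goblet, 13 colonocyte and 7 enteroendocrine markers were lower and 7 YAP targets and 8 fetal-like genes higher. Beyond p53 targets, Wnt targets, stem cell markers and cell cycle genes, the 12 other lists without a call had camera adjusted p-values from 0.103 to 0.752.

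limma called 49 of 11340 genes between KOWI and KO, 19 higher and 30 lower, with 1586 at an unadjusted p under 0.05. Beyond the lists, Bend4 (log2 2.96), Gpm6b (2.69), Tm4sf1, a membrane protein of migrating cells (2.27), Epdr1 (2.25), Dusp1 (2.14), Prrx2 (2.08), Fam149a (2.00), Zfp52 (1.96), Fam32a (1.69), St8sia4 (1.67), Zscan4c (1.59) and Zscan4a (1.57) rose. Sval1 (-3.91), Klk1b5 (-3.18), Spink1 (-2.94), the matrix protein Fbln1 (-2.83), Akr1c14 (-2.74), Sult1b1 (-2.55), Fam174b (-2.51) and Tex12 (-2.43) fell. The count was 0 with the scanner software's log ratios, with scaling between arrays (1472 at an unadjusted p under 0.05) or with outlier spots kept (1349), and 2544 with arrays taken as independent. It was 0 without KO replicate 2 or without KOWI replicate 2, and 209 without WT replicate 2.

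**Figure D2:**
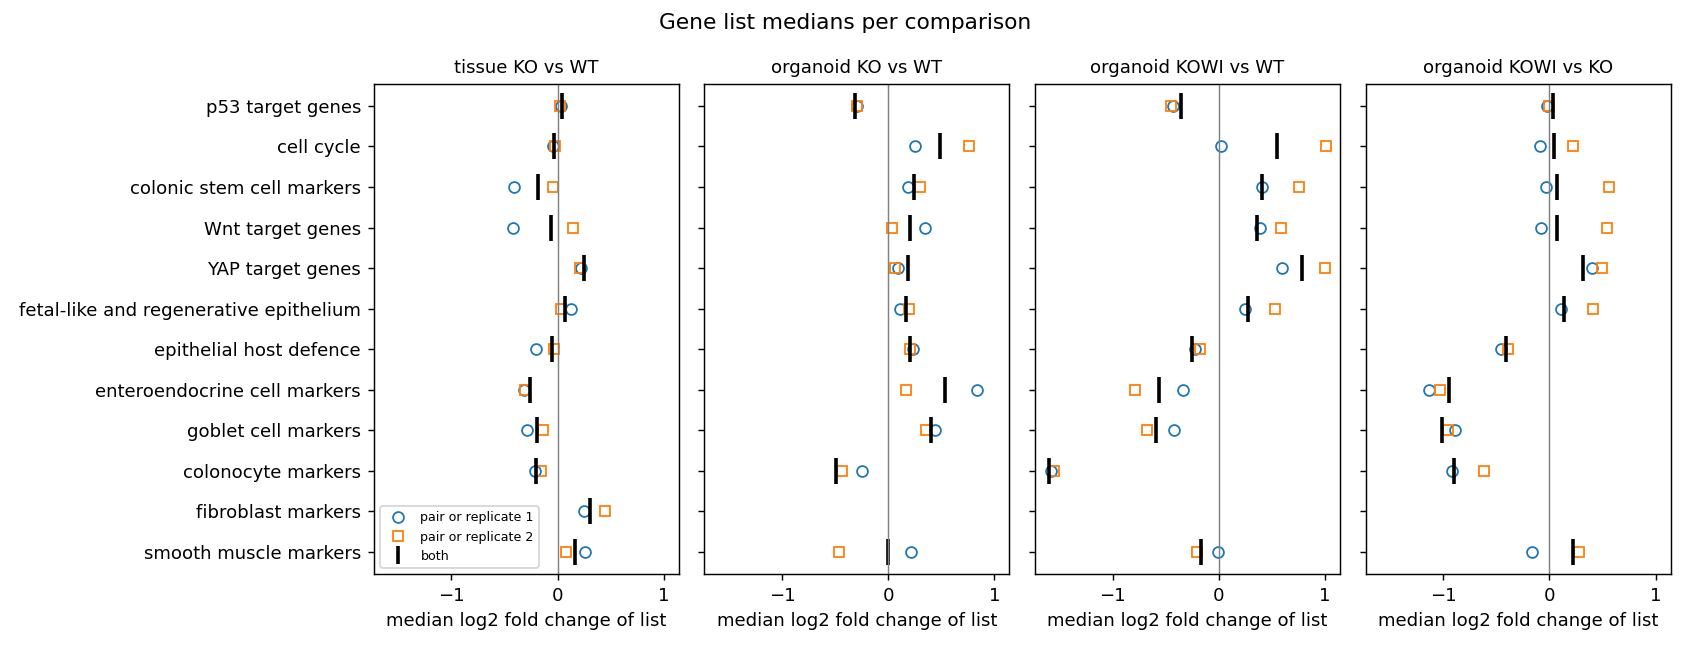
Median log2 fold change (x axis) of 12 gene lists (y axis) in the 4 comparisons, with a bar for the value over both pairs or replicates, a circle for number 1 and a square for number 2. Colonocyte markers had medians of -0.20, -0.49, -1.60 and -0.90 from left to right, and p53 targets 0.04, -0.31, -0.36 and 0.04.

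The 3 organoid comparisons share samples. Across genes, KO over WT and KOWI over WT correlated with r = 0.664, where simulated unchanged groups with the same shared WT samples gave 0.497; the covariance was 0.116 against a simulated 0.0274. With KO and KOWI taken from different replicates, which share no sample but are single values, r was 0.348 and 0.390 and the covariance 0.0896 and 0.0945. KO over WT and KOWI over KO had r = 0.187 against a simulated -0.497 (covariance 0.0249 against -0.0275). KOWI over WT and KOWI over KO had r = 0.859 against 0.506 (covariance 0.219 against 0.0281). They shared 19 higher and 28 lower genes, where independent lists would share 0.637 and 0.611. Simulated groups shared 0.05 in all, but held no changed genes and so hardly any calls. Independent lists leave out the shared KOWI samples, so neither value shows how much of this overlap those samples give. The simulated correlations and covariances already hold the shared samples. With different replicates the covariance was 0.0585 and 0.0633 for KO over WT with KOWI over KO, and 0.153 and 0.158 for KOWI over WT with KOWI over KO. Only for the latter was it below the excess over the simulated value, so part of that excess may come from the shared samples. Every organoid array joined a replicate 1 sample to a replicate 2 sample, which the simulation left out. Small gaps between these covariances therefore do not decide.

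The KO over WT ratios of tissue and of organoids were barely related across 9870 genes (Pearson r = 0.0743, Spearman rho = 0.115, across genes that are not independent replicates), and 52.5% had the same sign. limma called 0 genes with a different ratio (797 at an unadjusted p under 0.05, smallest adjusted p = 0.113). Of 167 genes at an unadjusted p under 0.05 in both, 90 had the same direction.

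**Figure D3:**
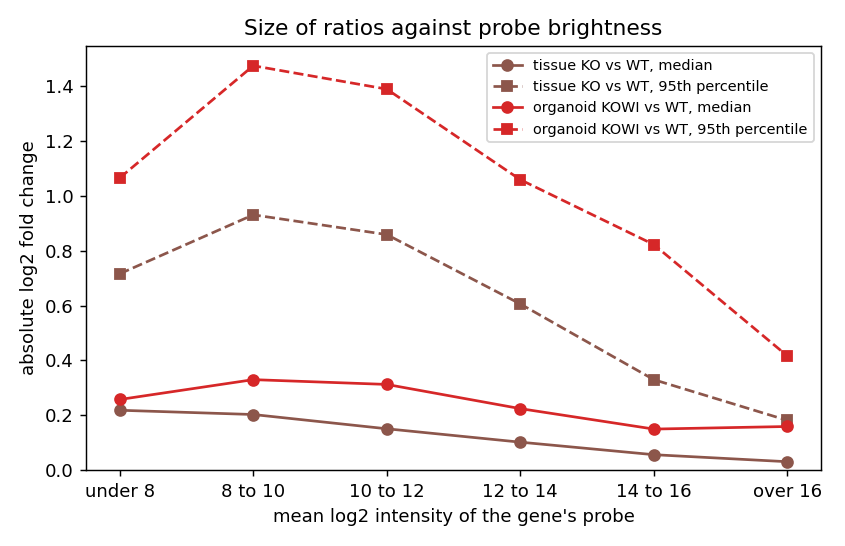
Absolute log2 fold change (y axis) by the mean log2 intensity of a gene's probe (x axis, 6 ranges) for KO tissue and KOWI organoids against WT, as medians (circles) and 95th percentiles (squares). The tissue median runs from 0.22 below an intensity of 8 to 0.03 above 16.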

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

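The tests of bright probes and of Trp53 itself were chosen after the result was seen, whereas the gene list comparison of tissue with organoids was planned.

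KO over WT ratios of gene lists differed between tissue and organoids in a camera test of the difference, for lists fixed before the data were examined. None of these differences passed with an estimated correlation, a test with little power in so few samples. p53 target genes had a mean log2 KO over WT of 0.03 in tissue and -0.50 in organoids, a difference of 0.526 (camera adjusted p = 2.73e-09; adjusted p = 0.108 with an estimated correlation). Goblet cell markers differed by -0.800 (adjusted p = 0.233 with an estimated correlation), enteroendocrine markers by -1.03 (adjusted p = 0.233), colonocyte markers by 0.192 (adjusted p = 0.233), host defence genes by -0.545 (adjusted p = 0.233), stem cell markers by -0.752 (adjusted p = 0.235), YAP targets by 0.187 (adjusted p = 0.307), Wnt targets by -0.702 (adjusted p = 0.458), cell cycle genes by -0.579 (adjusted p = 0.540) and smooth muscle markers by 0.211 (adjusted p = 0.597). Over genes with a probe under a log2 intensity of 14 in both, a choice made after the data were seen, the colonocyte difference was 0.129 (12 genes, SE over genes 0.280), that of smooth muscle 0.352 (3 genes, SE 0.252) and that of p53 targets 0.441 (25 genes, SE 0.163).

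For the p53 targets, shrunken ratios of bright probes as the whole cause are argued against: with probes under a log2 intensity of 14 the tissue median was -0.00891 over 29 genes (15 negative, SE of the mean 0.0522), against -0.263 in organoids with the same limit. As ratios shrink in part below 14 too, the limit was also set at 12, where the tissue median was 0.0655 over 23 genes (10 negative, SE of the mean 0.0614). The organoid median at this limit was -0.196 over 25 genes (19 negative, SE of the mean 0.131). Both medians were higher than at 14, so the contrast between them was of similar size. A candidate explanation is that few cells of the whole colon lost Trp53, since recombination was limited to Axin2-expressing cells and their progeny. The Trp53 ratio was less negative in tissue by 0.618 (SE 0.262, unadjusted p = 0.0542, adjusted p = 0.621). Trp53 was not well above background in KO organoids, so its fall there, and with it the difference, may be understated. The spread leaves the difference undecided, and as the probe may lie outside the deleted part, the explanation stays open. Differences that the design names, namely DSS injury, age of the lesion, culture, VillinCreERT2 in place of Axin2CreERT2 and the Nutlin-3A selection of KO organoids, stay open and untested.

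Probes without a gene name in the table used here also carried signal. Of 2185 such probes in organoids, 85 passed the threshold between KOWI and WT, 32 between KOWI and KO and 1 between KO and WT.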

How the results depend on the processing

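Keeping outlier spots, leaving out the high-background array, using only the direct KO and WT arrays, probes under a log2 intensity of 14 and the block for gene lists were chosen after seeing the data; all other alternatives were planned. The cause of a shift was not tested unless stated. In tissue the count of changed genes was 0 under every alternative but 1: 601 with arrays taken as independent (362 higher, 239 lower), which counts dye swaps as replicates. It was 0 without any single mouse, where the lone mouse is assumed to vary like the other group, and without the high-background array. Each pair alone, with no test, had 424 and 236 genes over 2-fold higher and 194 and 17 over 2-fold lower. KO against WT organoids went from 0 to 710 with arrays as independent and to 1 (Reg3b) with probes under 14, and ranged from 0 to 10 when a sample was left out (10 without KOWI replicate 1, 3 without KO replicate 1). KOWI against WT went from 611 to 134 with software log ratios, 275 with the series' value table (203 higher, 72 lower), 262 with no filter, which adds dim genes, 368 with scaling, 59 with outlier spots kept (44 higher, 15 lower), 930 with a spread shared with tissue and 4211 with arrays as independent, which included all 611. It ranged from 19 to 766 when a sample was left out (19 without KOWI replicate 2, 56 without WT replicate 1, 72 without KO replicate 2, 105 without WT replicate 2). KOWI against KO went from 49 to 0 with software log ratios, 4 with the value table, 4 with no filter, 25 with the stricter filter, 0 with scaling, 0 with outlier spots kept, 196 with a shared spread and 2544 with arrays as independent, which included all 49. It ranged from 0 to 209 when a sample was left out (0 without KO or KOWI replicate 2, 95 without KO replicate 1, 121 without KOWI replicate 1, 209 without WT replicate 2).

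The replicate number marks mice on the same array in tissue and the dye in organoids. Without the replicate block, on separate channels, tissue had 0 calls, KO against WT 0, KOWI against WT 788 (202 higher, 586 lower) and KOWI against KO 277 (53 higher, 224 lower). With the block on separate channels the organoid counts were 0, 616 (173 higher, 443 lower) and 173 (37 higher, 136 lower), so the use of separate channels, more than the block, moved the split. In KOWI against KO leaving out the block raised the separate-channel count from 173 to 277.

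Gene lists called by camera numbered 12, 9, 10 and 7 in the 4 comparisons. With an estimated correlation, a test with little power at 2 replicates, none was called in any (0, 0, 0, 0), and fry called 0, 2, 2 and 3. Leaving out a sample gave 10 to 14 lists in tissue, 5 to 15 for KO against WT (5 without WT replicate 1, 15 without KO replicate 2), 6 to 13 for KOWI against WT (6 without KOWI replicate 2) and 7 to 13 for KOWI against KO (13 without KO replicate 1, 12 without KOWI replicate 1). In tissue, leaving out a mouse also dropped the pairing, as separate channels were used. The direction of some lists against all other genes turned when a sample was left out, given here as list means. These were, in tissue, Wnt targets 0.737 (called, as was their lowest value) and stem cell markers 0.155 (not called) without WT replicate 1 (lowest, -0.957 and -0.629, without WT replicate 2) and T cell markers -0.131 without WT replicate 2 (highest 0.509, without WT replicate 1); in KO against WT without KO replicate 1, oxidative phosphorylation 0.104 and interferon-stimulated genes -0.130 (-0.171 and 0.659 without KO replicate 2); in KOWI against KO, oxidative phosphorylation -0.0303 without KOWI replicate 2, still negative but above the mean of other genes (-0.445 without KOWI replicate 1), and interferon-stimulated genes -0.357 and macrophage markers -0.936 without KO replicate 2 (highest 0.432 without KO replicate 1 and 0.0909 without WT replicate 1). The correlation of KO with KOWI effects went from 0.664 to 0.348 and 0.390 across replicates, which removes shared samples and also takes single values for means of 2; the covariance went from 0.116 to 0.0896 and 0.0945. The correlation was 0.657 with probes under 14, and that of tissue with organoid ratios went from 0.0743 to 0.0712. Over all alternatives, values of named genes lost the call 317 times and gained one 31 times in KOWI against WT, and 264 and 57 times in KOWI against KO.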

Other observations

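Of the tests below, the wider 2-cell-stage program and skeletal muscle in the KO tissue were written before their results were seen, and the comparisons with other cell types, with single arrays and with dye after; the lists of skeletal muscle, cornified skin, general epithelium and 2-cell-stage genes were added after the data were seen.

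Whole colon of both genotypes carried strong signal of skin and skeletal muscle. Krt10, a keratin of cornifying skin, had a mean log2 intensity of 17.5 and Myh4, a fast muscle myosin, 16.1 on the tissue arrays. Of 14 tested cornified skin genes, 7 of them also on the squamous list, 14 were positive in KO over WT (median 0.26), from Calm4 at 0.15 to Flg2 at 3.82 (SE 0.59, pairs 4.78 and 2.86), and none passed. Of 18 general epithelium genes, 4 of them on other lists, 0 were positive (median -0.14), with Cdh17 at -1.10 and Krt8 at -0.14.

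The 23 tested skeletal muscle genes all had positive values in KO tissue, with medians of 0.65 and 0.44 in the 2 pairs (camera p = 6.02e-14; p = 0.283 with an estimated correlation). The array with the high background as the cause is argued against: on the 3 arrays without the high background the lowest median was 0.353, on an array where the SE of the mean over the 23 genes was 0.0562, although the bound first written, 0.5 on each array, was not met. A lower share of epithelium that raises all other cell types alike would give skeletal and smooth muscle the same median. At probes under a log2 intensity of 14, skeletal muscle exceeded smooth muscle by 0.558 (9 and 10 genes). The SE of 0.0958 is over genes and not over mice, and the bound was rewritten after the values were seen. The lists were not matched for brightness within that limit, where ratios still shrink in part, so the gap does not decide. With the brightest probes the gap was 0.376, below the bound of 1 first written. Skeletal muscle from the pelvic floor or anal margin in the KO samples was weighed as a source, with bounds written beforehand. The bound for it, a median of at least 1 in each pair, was not met. The bound against it, a median below 0.5 in either pair, was met by the lower pair median of 0.443. That value lay within 1 SE of the mean over genes (0.0721) of 0.5, a margin that the bound did not name. Bright genes such as Tnnc2 (0.18) and Acta1 (0.43) understate the medians: 9 genes under 14 had a median of 0.88 and 14 above it 0.36 (Spearman rho of change with intensity -0.893). The explanation therefore stays undecided. What stays open is how much of the tissue contrast reflects where the colon was taken, which the labels do not give.

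Zscan4 genes, active in the 2-cell embryo and in cultured stem cells that elongate telomeres, rose in KOWI organoids and had positive values in KO organoids. Zscan4c, Zscan4a and Zscan4b were at 1.43, 1.30 and 1.21 in KO over WT (limma adjusted p = 0.203, 0.295 and 0.358), and rose by 3.02, 2.87 and 2.48 in KOWI over WT (adjusted p = 0.00658, 0.00815 and 0.00935). Dye bias or 1 array is argued against: the lowest ratio to WT of a Zscan4 gene on the 4 arrays with a WT sample was 1.00. A wider 2-cell-stage program may accompany them, since 10 of 10 other tested 2-cell-stage genes were positive in KOWI over WT with a median of 0.787 (camera p = 7.36e-05; p = 0.0537 with an estimated correlation), among them Zfp352 (1.31) and Usp17la (1.41), but the value lies between the bounds of 0.3 and 1 set beforehand. Of the 10, Tmem92 (at least 3.01-fold) and Tcstv1 were not well above background in WT, and the median was 0.787 also with these 2 at their bounds. As the Zscan4 copies share sequence, signal may come from any of them, and no test separated the copies.

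Wnt target genes were not called lower in KOWI than in KO organoids. With outlier spots kept, 13 of 22 had a positive value in KOWI over KO and their median was 0.03. This pattern was first chosen for weighing and, after its tests had been run, was replaced by the p53 targets, so no explanation is offered.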
